A study of Gallus gallus with 144 samples.

How the data were processed

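CAGE libraries were made by the authors from 5 µg of total RNA each with the nAnT-iCAGE protocol and molecular identifiers, per the labels' protocols. The labels give 12 libraries per combination of 6 tissues and 2 growth types, from 24 birds, each bird giving all 6 tissues. The submitters' processing notes name STAR 2.7.9a, UMI-tools 1.1.4 and the GRCg6a build. The peak caller's settings, the threshold of the peak set, the rule for promoter labels and the gene annotation behind them are not given in the sources used here. The name of the list calls it a robust set from decomposition-based peak identification.

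The deposited list gave 153662 peaks, each with a sequence, start, end, strand, a representative position inside the peak, a promoter label and a gene name. Starts were counted from 0 and are printed 1-based. The BED score column and 1 further column held the value 1 in every row of the deposited list, so neither ranked peaks. The meaning of the representative position was read from the values. No column belonged to a library, so depth per library is unknown, and intervals and tests below cover counting over genes or peaks only. For this reason the planned tests of fast against slow growth and of tissue against tissue, the score comparisons and the paired analysis by bird were not run. No genome sequence or annotation of GRCg6a was used here, so the planned TATA, initiator, GC content and peak location results were not run. The authors' promoter label took the place of the planned windows around annotated start sites.

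Sequences were given chromosome names by hand, and 8101 of 8112 labelled genes compared (99.9%) lay on the same chromosome in the RefSeq table of the GRCg7b assembly, which was used for names and gene order only. The 75 labelled genes on chromosomes 32 and 33 were left out of this comparison, since GRCg7b numbers these chromosomes differently and none of the 75 had the same number. Of the 8604 symbols in the list, 8188 matched that table and 139 more matched through older symbols. A further 1833 genes were named by an Ensembl identifier and were not matched to symbols. In list tests, a gene labelled only under such an identifier or an unmatched symbol counted as unlabelled. Of 605 genes in 22 lists, 544 were measurable, that is, protein-coding with a current symbol in the table. Lists of sampled tissues, tissues not sampled, functions and other cell types were fixed before the data were examined.

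Each list was tested with Fisher's exact test, two-sided, against all other of the 14357 symbol-bearing protein-coding genes, with Benjamini-Hochberg adjustment. Shares have 95% Wilson intervals. For 10430 genes with all promoters on 1 sequence and strand, promoters over 100 bp apart counted as separate, and 7 genes with labels on more than 1 sequence or strand were left out. List means were set against 10000 random lists matched on chromosome class, for lists with at least 5 such genes. Downstream peaks were unlabelled peaks 500 to 20000 bp past the first promoter peak. Divergent pairs were adjacent peaks with representative positions 0 to 400 bp apart, compared with 100 sets of uniformly shuffled positions. The plan called for counts only where chromosome lengths were not used. The span from first to last peak was used as length instead, a choice made after the data were seen, and permutation tests had 100000 resamples. Named genes were all members of the growth list, up to 4 members of each other list with the most promoter peaks and up to 4 without a label, the 10 genes with the most separate promoters, and the 5 widest peaks. Some genes that this rule takes are not reported here.

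Tests used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. On simulated labels over the same 14357 genes, lists planted at a share of 90% were called in 85.9% of cases and lists left at the overall share in 1.36%, over 20 runs. Only the glycolysis list stood above 90%, so the power at the shares of the other lists is not known. The pair counter found 500 of 500 planted pairs. The alternatives tried were other distances, merged neighbouring peaks, assembled chromosomes only, peaks over 1 bp wide only, older symbols, a lung list without TTF1, other backgrounds and other downstream windows.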

Results

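Transcription start sites were mapped by CAGE, which sequences the capped 5′ ends of RNA, in 6 tissues of 24 chickens. Brain, breast muscle, heart, kidney, leg muscle and liver were each taken from 12 fast-growing and 12 slow-growing birds, giving 12 groups of 12 libraries. The measurement analysed here was 1 pooled list of 153662 peaks on the GRCg6a build, with no value per library and no replicates. Depth per library and the height of each peak were therefore unknown. Fast against slow growth, and tissue against tissue, were not analysed here. The questions below concern which genes the pooled birds and tissues gave a promoter peak, how many promoters those genes had, and where the remaining peaks lay.

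Genes typical of the sampled tissues carried the authors' promoter label far more often than genes typical of tissues that were not sampled. Of 108 marker genes of skeletal muscle, heart, liver, kidney and brain, 81 had a labelled promoter peak (75%, 95% Wilson interval 66.1 to 82.2). Of 82 marker genes of oviduct and ovary, testis, eye, pancreas and gut, and lung, 19 did (23.2%, interval 15.4 to 33.4). The odds ratio between these sets was 9.95 (Fisher's exact test, two-sided, p = 7.48e-13). Without TTF1, discussed below, the second set stood at 18 of 81 (22.2%) and the odds ratio at 10.5. This pooling of the lists was chosen after the list values were seen, as was leaving out TTF1. Among all 14357 protein-coding genes with a symbol, 8184 had a label (57.0%, interval 56.2 to 57.8). Genes labelled only under an Ensembl identifier or an unmatched symbol counted as unlabelled, so this share and those of the lists are lower limits. Genes are not independent replicates, and a missing label did not show that a gene had no peak.

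Of the sampled tissues, heart muscle genes were labelled in 18 of 22 cases (81.8%, adjusted p = 0.0399). The named genes were CASQ2, the calcium-binding protein of the sarcoplasmic reticulum, with 6 promoter peaks, NKX2-5, a cardiac transcription factor, with 5, and HAND2 and MYL3 with 3 each. MYL2, PLN and RYR2 had no label. Brain genes were labelled in 17 of 22 cases (77.3%, adjusted p = 0.151). ELAVL4, a neuronal RNA-binding protein, had 11 promoter peaks, AQP4, the astrocyte water channel, 10, MBP, a myelin protein, 10, and CAMK2A 7. GAD2, MOG, NEUROD6 and RBFOX3 had none. Kidney genes were labelled in 16 of 21 cases (76.2%, adjusted p = 0.151), among them EMX1 with 5 peaks, and LRP2 and SLC22A7 with 2 each. KCNJ1, SLC12A1 and SLC12A3 had no label. Liver genes were labelled in 18 of 24 cases (75%, adjusted p = 0.165), with AMBP at 4 peaks and HPD at 3. ALB, APOA1, C3 and FGB, genes of abundant plasma proteins, had none. Skeletal muscle genes were labelled in 12 of 19 cases (63.2%, adjusted p = 0.752). MYBPC3 had 8 peaks, and CACNG1, CAV3 and PVALB had 4 each, while CACNA1S, MYBPC2, MYF6 and MYLPF had none. A peak of the pooled list may come from any sampled tissue. The peaks of MYBPC3 thus cannot be assigned to skeletal muscle rather than heart, nor those of EMX1 to kidney rather than brain. The adjusted values came from Fisher's exact tests of each list against all other symbol-bearing protein-coding genes, Benjamini-Hochberg adjusted over 22 lists. The call for heart was lost when older symbols were matched too, though the share stayed at 81.8% (adjusted p = 0.063). It was also lost without promoter peaks of 1 bp (68.2%, adjusted p = 0.446) and with at least 2 promoter peaks asked for (50%, adjusted p = 0.438).

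**Figure D1:**
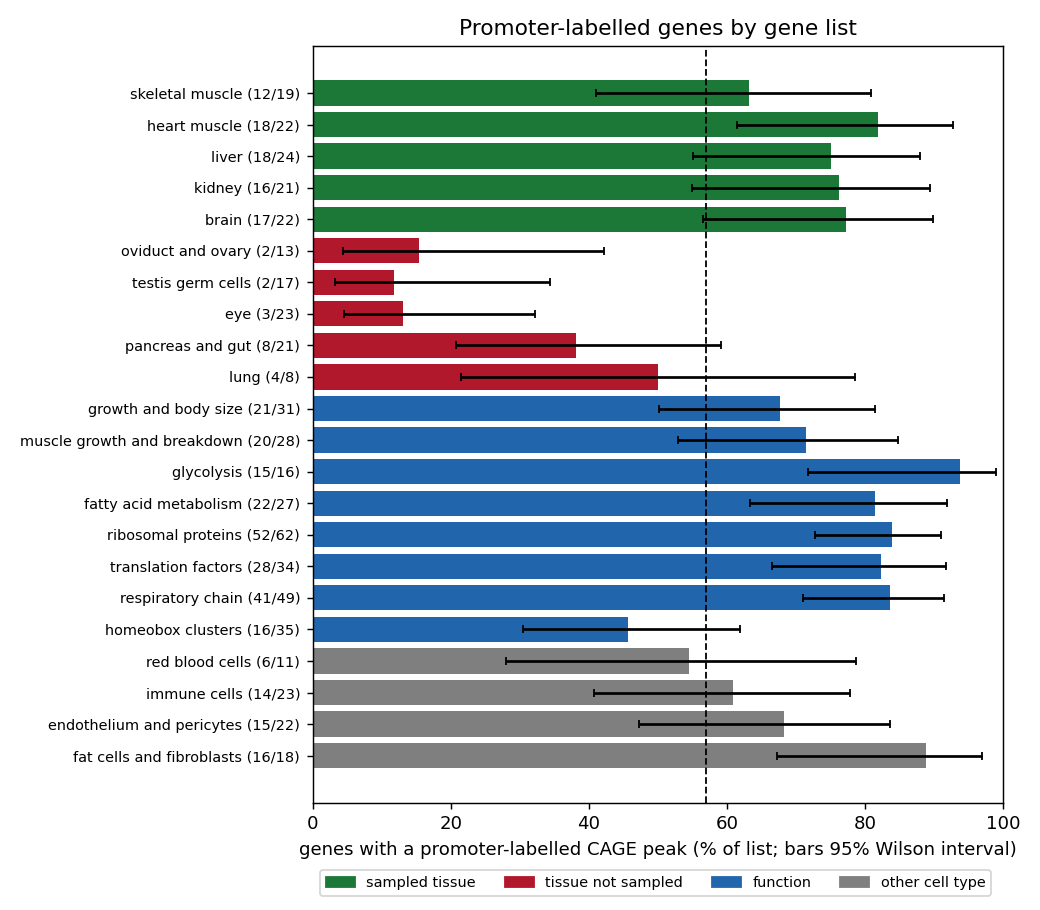
Percent of each gene list with a promoter-labelled CAGE peak (horizontal axis, 0 to 100%), by list, with 95% Wilson intervals and the number labelled over the number measured; colours give the kind of list and the dashed line marks the 57.0% of all symbol-bearing protein-coding genes. The eye list lies lower than all but the testis list at 13.04% and the glycolysis list highest at 93.8%.

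Genes of the eye, testis and female reproductive tract were labelled less often than other genes. In the eye list 3 of 23 genes had a label (13.04%, adjusted p = 0.000211), namely RLBP1 with 2 promoter peaks and CRYBB2 and PDE6B with 1 each. ARR3, BFSP1, BFSP2 and CRYAA were among the 20 without. In the testis germ cell list 2 of 17 had a label (11.8%, adjusted p = 0.00123), CREM and SPATA4 with 3 peaks each. BOLL, DAZL, DDX4 and DMC1 were among the 15 without. In the oviduct and ovary list 2 of 13 had a label (15.4%, adjusted p = 0.0104), AVD and ZP1 with 1 peak each. BMP15, CYP19A1, GDF9 and NOBOX were among the 11 without. The pancreas and gut list did not pass the test, with 8 of 21 genes (38.1%, adjusted p = 0.189), nor did the lung list, with 4 of 8 (50%, adjusted p = 0.805). SST, a neuropeptide also made in brain, had 2 promoter peaks but was not among the 21 genes tested. AMY2A, CEL and CELA1 had 1 each. CDX1, CDX2 and FABP6 had none. In the lung list LAMP3, NKX2-1 and SFTPA1 had 1 peak each and TTF1 had 3, while ABCA3, CLDN18, FOXJ1 and HOPX had none. The lung marker once called TTF1 is NKX2-1, while the gene with the symbol TTF1 encodes a termination factor of RNA polymerase I and does not belong in a lung list. Without it the list stood at 3 of 7 genes (42.9%, adjusted p = 0.547). Pancreas and gut genes fell below other genes when at least 2 promoter peaks were asked for (0% of the 21 tested, which leave out SST, adjusted p = 0.00108). The testis call was lost in that setting (adjusted p = 0.0806).

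Genes of energy metabolism and protein synthesis were labelled more often than other genes. Glycolysis genes led with 15 of 16 (93.8%, adjusted p = 0.0085). ENO1, HK1 and PFKP had 4 promoter peaks each, and ALDOA was the member without a label. Ribosomal protein genes followed with 52 of 62 (83.9%, adjusted p = 0.000179), with RPL22 at 6 peaks and RPL14, RPL21 and RPL32 at 3. RPL19, RPL23, RPLP0 and RPLP1 were among the 10 without. Respiratory chain genes reached 41 of 49 (83.7%, adjusted p = 0.000868). NDUFS5 had 5 peaks, NDUFS1 and UQCRQ 4, and COX7A2 3, while ATP5PB, COX4I1, COX6C and COX7C had none. Translation factors reached 28 of 34 (82.4%, adjusted p = 0.00992), with 3 peaks each at EIF2S1, EIF3B, EIF3D and EIF4A2 and none at EEF1B2, EEF1G, EIF3K and EIF4B. Fatty acid metabolism reached 22 of 27 (81.5%, adjusted p = 0.0258). LPIN1 and PPARA, the latter a regulator of fatty acid oxidation, had 6 peaks and ACACA 5, and ACLY, ELOVL6, FADS1 and HADHB had none. Of these calls, those of ribosomal proteins, translation factors and fatty acid metabolism were lost when promoter peaks of 1 bp were left out (adjusted p = 0.677, 0.229 and 0.288). All 5 were lost when at least 2 promoter peaks were asked for, which 38.4% of all genes had. Glycolysis then stood at 62.5% (adjusted p = 0.138), fatty acid metabolism at 59.3% (0.0817), the respiratory chain at 55.1% (0.0806), translation factors at 44.1% (0.594) and ribosomal proteins at 25.8% (0.12).

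The remaining lists covered other cell types and developmental regulators. Fat cell and fibroblast genes were labelled in 16 of 18 cases (88.9%, adjusted p = 0.0193), a call lost without promoter peaks of 1 bp (adjusted p = 0.0608) and with at least 2 peaks asked for (adjusted p = 0.49). FBLN1 had 9 promoter peaks, ADIPOQ, the adipocyte hormone adiponectin, and DCN had 7, and POSTN had 4, while LEPR and LUM had none. The others did not pass the test. Endothelium and pericyte genes stood at 15 of 22 (68.2%, adjusted p = 0.476), with TIE1 at 5 peaks, FLT4 at 4, and ERG and SOX18 at 3. ESAM, MYH11, PDGFRB and PROX1 had no label. Immune cell genes stood at 14 of 23 (60.9%, adjusted p = 0.874), with BTK, CD3D and CD8A at 4 peaks and CD3E at 3. CD28, CD4, CSF3R and IL7R had none. Red blood cell genes stood at 6 of 11 (54.5%, adjusted p = 1). TAL1 had 2 peaks and BPGM, HBA1 and HBAD 1 each, and EPB42, HBBA, HBE and RHAG had none. Homeobox cluster genes stood at 16 of 35 (45.7%, adjusted p = 0.318). HOXA6, HOXB4, HOXC10 and HOXD8 had 3 peaks each, and HOXA10, HOXA13, HOXA4 and HOXA7 were among the 19 without a label.

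The birds were chosen for their growth, and 21 of the 31 growth and body size genes had a labelled promoter (67.7%, adjusted p = 0.359, not past the test). INSR, the insulin receptor, had 6 promoter peaks between positions 4253124 and 4253350 of chromosome 28, the most in the list. FTO, NCAPG, SOX5 and TBC1D1 had 3 each. GH, growth hormone, had 2 on chromosome 27 (4038379 to 4038509), the wider of them 80 bp, and IGF1R had 2 on chromosome 10 (17264867 to 17265053), 182 bp apart. IGFBP3 and PRKAG3 also had 2. A single promoter peak was labelled for GHR, GHRHR, HMGA2, IGFBP1, IGFBP2, IGFBP4, IGFBP5, LCORL, MC4R, POMC, RB1 and THRSP. LCORL and NCAPG, neighbours in a region tied to body size in several species, lay on chromosome 4 with promoters at 75821293 and 75920673, on the plus and minus strands. CCKAR, GHSR, IGF1, IGF2, IGF2BP1, IGF2R, IGFBP7, MSTN, SOCS2 and TSHR had no label under these symbols. With older symbols matched too, the share rose to 74.2% (Fisher's exact test, adjusted p = 0.131). Some of these genes thus matched a labelled older symbol. Muscle growth and breakdown genes were labelled in 20 of 28 cases (71.4%, adjusted p = 0.192). TGFB2 had 4 peaks and EIF4EBP1, INHBA and MEF2A had 3, while ACVR2B, AKT1, BMP2 and CAPN1 had none under these symbols. Matching older symbols raised this share too, to 75% (Fisher's exact test, adjusted p = 0.131).

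Brain genes stood apart in how many promoter peaks they had. The 17 labelled brain markers averaged 4.82 promoter peaks each, against 2.39 over the 10430 genes whose promoters lay on 1 sequence and strand. That mean lay above all 10000 random lists of the same size and chromosome classes. Ribosomal protein genes averaged 1.48, below every random list. Also below the central 95% of random lists lay pancreas and gut (1.11 peaks), red blood cells (1.17), kidney (1.63), homeobox clusters (1.65), translation factors (1.75) and the respiratory chain (1.93). Growth and body size genes averaged 1.81, at percentile 3.055, liver genes 1.78, at percentile 3.945, and muscle growth and breakdown genes 1.85, at percentile 5.225. Without the highest gene of each list, INSR in the growth list, these fell below the central 95%, to percentiles 0.28, 0.86 and 2.105. Taking out the highest gene can only lower a mean, and the random lists kept theirs. Brain stayed above, at percentile 99.99. Of the 10430 genes, 1984 had promoter peaks over 100 bp apart (19.02%, Wilson interval 18.3 to 19.8), and 645 had them over 500 bp apart. In separate promoters brain did not stand alone. Brain (mean 1.88) and heart muscle (1.61) both lay above the central 95% of random lists, each with a median of 1. Respiratory chain (1.05) and endothelium and pericyte genes (1) lay below it, and all genes averaged 1.24. The genes with the most separate promoters included NTM, ANK3 and MBP with 7 each, MGLL, ELAVL4, SH3PXD2A, SORBS2 and RAB27A with 6 each, and TSPAN4 with 5. NTM, a neuronal cell adhesion gene, also had the most promoter peaks of any gene, 20 over 140542 bp of chromosome 24 from 1893560 to 2034121. The promoters of ANK3, which encodes an ankyrin of axons and other cells, spread over 187525 bp of chromosome 6, and those of MBP over 90219 bp of chromosome 2. The longest spread was that of LSAMP, a limbic system adhesion gene, at 678999 bp on chromosome 1. The random lists describe this 1 peak set and give no p-value, and they were chosen after the data were seen.

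Most peaks lay outside labelled promoters. Labels covered 24969 peaks (16.2%, Wilson interval 16.1 to 16.4) and named 10437 genes, of which 3758 had 1 labelled peak and 984 had 5 or more. Promoter peaks were wider than the rest, with a median of 9 bp against 7 bp. A width of 1 bp was found for 1415 promoter peaks (5.67%) and 35003 unlabelled peaks (27.2%), and a width over 100 bp for 290 (1.16%) and 266 (0.207%). The widest peak of all, on chromosome 7 (22174463 to 22175204, minus strand), was the promoter of DES, the muscle intermediate filament desmin. The others among the 5 widest were a 726 bp unlabelled peak on chromosome 5 (8234841 to 8235566, minus strand), the 710 bp promoter of GAPDH on chromosome 1 (77619181 to 77619890), the 692 bp promoter of EHD2 on chromosome 32 (228039 to 228730), and the 668 bp promoter of GPI on chromosome 11 (10964309 to 10964976). The nearest labelled promoter on the strand of the unlabelled one was that of MICAL2, 123824 bp away. GAPDH and GPI are glycolytic enzymes.

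Unlabelled peaks gathered on the transcribed strand downstream of muscle, liver, brain and glycolysis promoters. From 500 to 20000 bp past the first promoter peak, glycolysis genes had on average 13.7 unlabelled peaks on their own strand and 3.40 on the opposite strand. Liver genes had 13.1 and 3.94, skeletal muscle genes 9.33 and 2.50, brain genes 8.82 and 5.06, homeobox genes 8.06 and 2.29, and heart muscle genes 7.22 and 2.50. All 10430 genes averaged 2.43 and 1.88. The difference between strands lay above the central 95% of random lists for 9 of 18 lists, the others being translation factors (mean difference 3.86), ribosomal proteins (1.88) and fat cells and fibroblasts (4.38). Kidney genes (2.38 and 1.13) and growth and body size genes (2.24 and 2.05) lay at percentiles 80.5 and 39.4. Without their highest gene, brain lay at percentile 89.3, ribosomal proteins at 96.2 and fat cells and fibroblasts at 95.5. With windows to 50000 bp ribosomal proteins lay at 83.5, while fatty acid metabolism moved from 97.465 to 97.545, just past the limit of 97.5. These windows were chosen after the data were seen, and those of neighbouring genes overlap. Windows of homeobox genes can also take in unlabelled homeobox genes. The stretch between HOXB7 and HOXB4 held 3 such genes, HOXB3, HOXB5 and HOXB6, with 32 peaks on the plus strand and 7 on the minus strand.

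**Figure D2:**
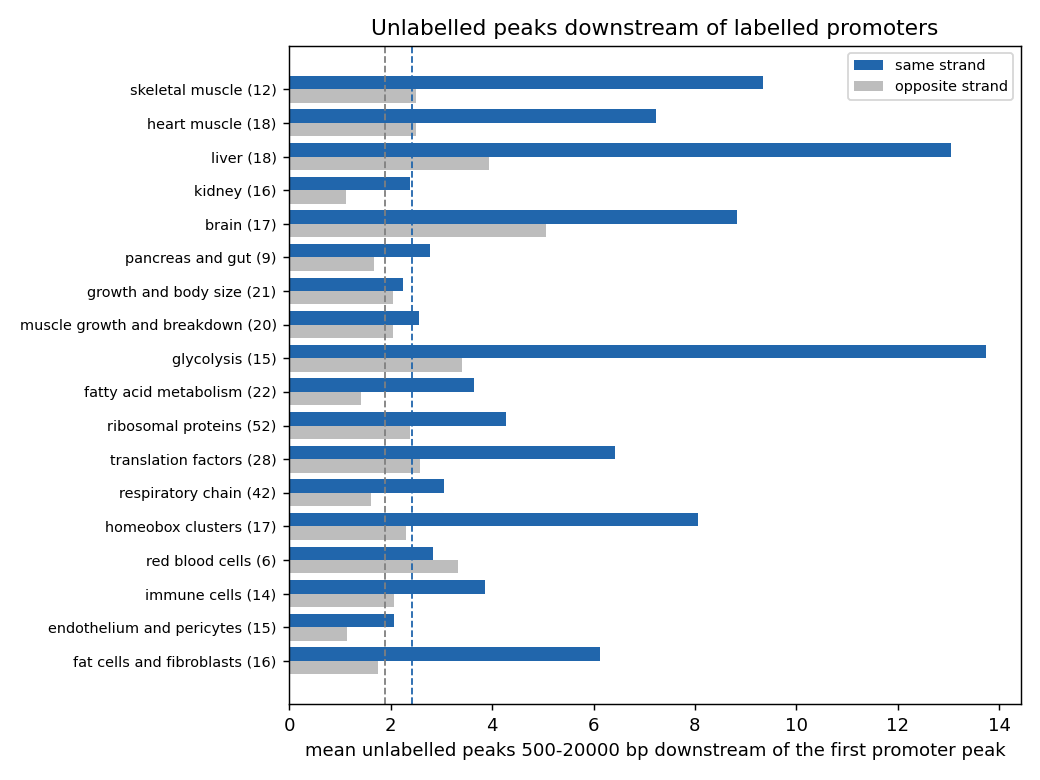
Mean number of unlabelled peaks 500 to 20000 bp downstream of the first promoter peak (horizontal axis), on the gene's own strand (blue) and the opposite strand (grey), for the 18 lists with at least 5 labelled genes; dashed lines mark the means over 10430 genes, 2.43 and 1.88. Glycolysis and liver genes have the longest blue bars, 13.7 and 13.1.

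Single genes with long runs on their own strand, chosen after their values were seen, included the fast myosin heavy chain genes of chromosome 18. MYH1F had 109 unlabelled peaks downstream on its own strand and 9 on the other, MYH1E 102 and 1, and MYH1A 77 and 5. Between 350001 and 700000 of that chromosome, 486 of 541 peaks lay on the minus strand and 8 carried a promoter label. Outside this cluster, the longest runs followed gga-mir-7474 (60 and 0) and ENSGALG00000051776 (57 and 1) on chromosome 7. Their plus-strand promoters began at 15347724 and 15337776, so their windows overlap and share peaks. Dense plus-strand peaks also lay before both promoters, with 60 between 15300001 and 15320000. These runs thus cannot be given to either gene. The fibrinogen gene FGG had 52 and 2, the pyruvate kinase gene PKLR 45 and 2, GAPDH 42 and 3, and the collagen gene COL1A1 39 and 3. The window of FGG took in the labelled promoter of FGA, which had 37 and 34 in its own window. The 52 peaks thus cannot be given to FGG alone.

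**Figure D3:**
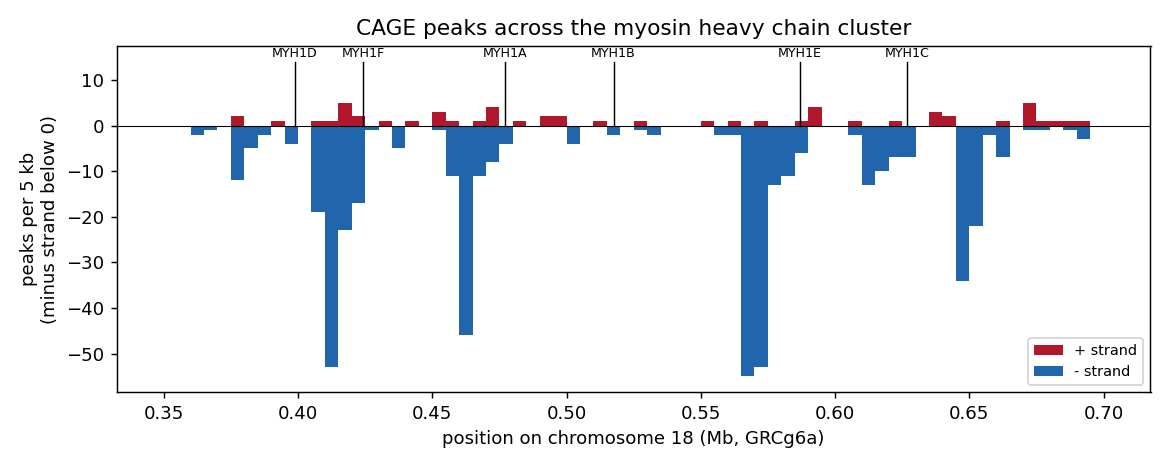
CAGE peaks per 5 kb across the myosin heavy chain cluster of chromosome 18 (horizontal axis, position in Mb on GRCg6a), plus strand above 0 and minus strand below, with vertical lines at the labelled promoters of MYH1 genes. The minus strand holds 486 of the 541 peaks.

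Divergent pairs, a minus-strand peak followed by a plus-strand peak within 400 bp, mark bidirectional promoters and candidate enhancers. There were 3789 such pairs, against 2384 ± 48.2 (SD, 100 sets) after positions were shuffled within sequences and 2815 pairs in the convergent orientation. The convergent count also exceeded the highest shuffled set, 2535. Uniform shuffling does not keep the clustering of peaks, so the excess over it is not particular to divergent pairs. Divergent pairs numbered 1.35 per convergent pair. Both members were promoters of different genes in 600 pairs, and 1806 pairs (47.7%) had no labelled promoter within 500 bp. Respiratory chain promoters were in such pairs more often than other labelled genes, 18 of 41 against 22.4% (43.9%, Fisher's exact test, adjusted p = 0.04 over 18 lists), among them NDUFA1 with UPF3B and NDUFB1 with CPSF2. Ribosomal protein genes stood at 36.5% (adjusted p = 0.176), and none of the 15 endothelial or 14 immune genes was in a pair (adjusted p = 0.184 and 0.225). This list test was chosen after the data were seen. Within 1000 bp, the 5728 pairs did not exceed the highest shuffled set, 5783.

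Peaks lay more densely on small chromosomes. The 5 large chromosomes held 76523 peaks at 126 per Mb of the span from first to last peak, the 5 intermediate ones 156 per Mb and the 22 small ones 213 per Mb. Density fell with span over 34 chromosomes (Pearson's r = -0.747 with the logarithm of the span, Spearman's rho = -0.808). Permutation tests, two-sided, gave p = 1e-05 for each, the smallest that 100000 resamples can give (adjusted p = 1.67e-05 and 1e-05 over 5 settings). Without chromosomes 1 and 32, the farthest from the median span on a logarithmic scale, r was -0.691 (permutation test, p = 4e-05). That setting was not planned in advance. The span is also the denominator of the density, which limits the test. The Z chromosome held 9382 peaks at 114 per Mb, below the lowest autosome at 117 per Mb. The W chromosome held 23, at 3.44 per Mb, with no label. The share of peaks with a promoter label was 14.5% (interval 14.2 to 14.7) on large and 20.3% (19.95 to 20.7) on small chromosomes.

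**Figure D4:**
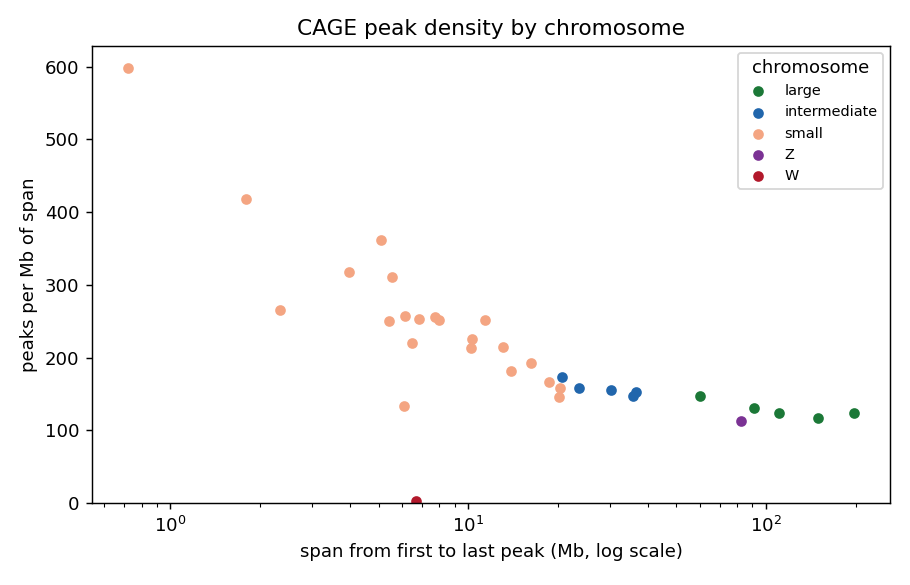
Peaks per Mb of span (vertical axis) against the span from the first to the last peak (horizontal axis, Mb, log scale) for 34 chromosomes, 1 point each, coloured by class. Small chromosomes reach 599 per Mb, large ones lie between 117 and 148, and W lies at 3.44.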

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

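The settings for older symbols, TTF1, peaks over 1 bp, at least 2 promoter peaks, locus-number genes, downstream windows and the label share were chosen after the data were seen. No paired analysis was possible because the pooled peak list carries no values per library. The settings fixed in advance with windows around annotated start sites, score cut-offs, sequence motifs, GC content and count normalization were not run, and leaving out replicates did not apply. Merged peaks, promoter peaks only and leaving out Z and W kept the fall in density with chromosome span and its side of the threshold. The share of labelled peaks moved from 16.2% to 16.5% on assembled chromosomes only, to 20.1% for peaks over 1 bp wide and to 10.6% after merging same-strand peaks within 100 bp. The share of labelled genes moved from 57.0% to 54.8% for peaks over 1 bp wide. With locus-number genes it was 45.4% and 14 lists passed, but matching by symbol gave none of the added genes a label, so that setting fixed its outcome and tests no call. Lists past the threshold went from 10 (7 above other genes, 3 below) to 3 with at least 2 promoter peaks per gene (0 above, 3 below). They went to 5 for peaks over 1 bp wide (2 above, 3 below) and 9 with older symbols (6 above, 3 below), and stayed at 10 without TTF1. Asking for at least 2 promoter peaks lowered ribosomal proteins from 83.9% to 25.8% (adjusted p = 0.12) and all genes from 57.0% to 38.4%. Genes with several promoters fell from 1984 to 645 at 500 bp, as the stricter distance requires, and divergent pairs rose from 3789 to 5728 at 1000 bp. The cause of the other shifts was not tested. Depth is unknown, so a gene without a label cannot be called silent.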

Other observations

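The tests of older symbols, of neighbouring copies, of peak density around unlabelled markers and of abundant transcripts were chosen only after the result was seen. The test of that density outside the bodies of labelled neighbours was added after the density was seen, with its prediction written before its own value was. The stretches described next were also picked after their values were seen. Stretches of dense one-sided peaks also lay around genes without a label. Between the labelled neighbours ANKRD17 and EPHA5 on chromosome 4, a stretch that holds ALB and 5 other unlabelled genes, 104 unlabelled peaks lay on the plus strand and 20 on the minus strand. The stretch of MYOZ1, a protein of the muscle Z-disc, held 38 and 5. Outside the bodies of the labelled neighbours these stretches still held 88 and 16, and 20 and 4. By contrast, the stretch of MSTN, which encodes the muscle growth inhibitor myostatin, held 5 and 11, or 10.6 per 100 kb on the denser strand, and that of IGF1 22 and 12, or 6.48, against a median of 9.22 over all 2959 stretches. The stretch of IL7R held 2 and 1, and that of GUCA1A, a photoreceptor gene, held none.

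Several values belong to no comparison. The mitochondrial genome held 121 peaks, 92 of them on the minus strand. On the W chromosome 13 of 23 peaks were 1 bp wide (56.5%), against 23.7% of all peaks, and none of 12 named W genes had a label, against 395 of 671 on Z (58.9%). The sex of the birds is not given in the labels used here. Peak widths of 6 and 11 bp were overrepresented, with 8562 peaks of 6 bp beside 6822 of 5 bp and 6712 of 7 bp, and 7815 peaks of 11 bp beside 4888 of 10 bp and 3644 of 12 bp. In 64.9% of the 11 bp peaks the representative position was the central base.

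Of the markers of sampled tissues, 27 had no promoter label. Older symbols recovered none of them (0%), which argues against an older symbol held by the RefSeq table as the cause. Symbols that matched nothing in that table, and the 1833 genes named by an Ensembl identifier, could not be tested in this way. Other changes of name therefore remain open. A candidate explanation is that peaks were present and received no gene name: stretches around unlabelled markers of sampled tissues held more peaks per 100 kb on their denser strand than those of tissues not sampled (medians 16.5 and 8.40, 22 and 52 stretches). The mean log2 difference was 0.97 (0.9733, permutation test, two-sided, p = 0.00121). Peaks within the labelled neighbours are argued against as the whole cause where this could be tested. Outside the bodies of these neighbours (table length, at least 20 kb from the promoter) the mean log2 difference was 0.772 (0.7721, p = 0.0182), over 18 and 43 stretches with at least 5 kb left. Over the same stretches the difference was 0.689 with those bodies kept (p = 0.0116). The stretches of FGB, APOA1, TCAP and SLC12A3, at 161, 45.3, 87.5 and 10.5 peaks per 100 kb, had less than 5 kb left, so their peaks remain open to this explanation. Promoters named only by an identifier lay in 36.36% of these stretches and in 29.1% of all stretches (Fisher's exact test, p = 0.482), which leaves that explanation open. No biological explanation was tested, and other genes within a stretch may supply part of its peaks.

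Runs of at least 20 unlabelled same-strand peaks followed 94 nuclear promoters. Sharing of reads between neighbouring copies of a family, as in the MYH1 cluster, is argued against as the whole cause only as far as symbols show relatives. Of the 65 named genes in the gene order, 15.38% had a gene of the same symbol stem among the 5 next genes on either side (Wilson interval 8.58 to 26.1). Among all labelled genes the share was 5.66%. Genes named by an identifier were not scored, and FGG, near FGA, was not counted as having a relative. A symbol stem does not measure shared sequence, so relatives with other symbols remain open. Unlabelled neighbours could supply some of the peaks: genes with a run had 0.6099 more unlabelled genes next to them (means 2.69 and 2.08), a difference that did not pass the permutation test (p = 0.123). RNA ends within abundant transcripts may contribute, since 7 of the 9 lists of sampled tissues and abundant housekeeping products exceeded the central 95% of random lists. Kidney and respiratory chain genes did not, however. Homeobox genes did, though their windows can hold unlabelled homeobox genes. Abundance was not measured here. No biological explanation was tested.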
